A study of Mus musculus with 17 samples.

How the data were processed

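Counts came from 17 libraries of sorted mouse testis cells, 4 GFRA1pos, 4 GFRA1neg, 5 KITpos and 4 P6gonocyte, grouped by the sample titles. The column read as GFRA1pos replicate 1 is spelled with GFP in place of GFR in the deposited table; it was taken as a slip, because it is the sole column left for that title, and the GFRA1pos values rest on this reading. Per the labels' protocols, testes were dissociated with enzymes, with a first digestion to remove interstitial cells. RNA of the sorted cells was amplified with the NuGEN Ovation V2 kit and sequenced as TruSeq V2 libraries with paired-end reads on an Illumina HiSeq. The deposited table held raw whole-number counts per gene, with no normalization by the authors that its values show. The submitters' processing notes name the mm9 build, Trim Galore, TopHat2 2.0.4, Bowtie2 2.0.0-6, DESeq2, Bowtie and DESeq without their roles, and the counting program, its annotation and its use of strand are not given in the sources used here. Counts of a gene and an antisense or overlapping partner therefore could not be told apart. The labels name no batch, date or animal.

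The table had 24013 rows identified by Entrez gene number. Symbols were matched by number for 23930 rows with a RefSeq gene table of the GRCm38.p6 assembly, used for names only, and 83 rows had no match. A total of 1179 rows with counts had the same counts in every library as another row. Totals per library ran from 5178352 to 12641907 counts. The chi-square per degree of freedom between replicate libraries ran from 3.89 to 46.5 over 28 pairs, above the 1 that counting error alone would give.

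Differences were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F-test on all 17 libraries with 1 mean per group, TMM scaling, filterByExpr by group, Benjamini-Hochberg adjustment, adjusted p under 0.05). The test covered 15451 genes, with a common biological coefficient of variation of 0.30 and 6.08 prior degrees of freedom. Each value given as ± SE is a log2 fold change with its standard error, and CPM values use TMM-scaled library sizes. Folds against a group with 0 counts were computed against a floor of 3 counts over the libraries of that group. Comparisons were GFRA1pos minus GFRA1neg, KITpos minus GFRA1neg and P6gonocyte minus GFRA1pos, with counts of genes alone for KITpos minus GFRA1pos and P6gonocyte minus GFRA1neg.

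A set of 30 gene lists was fixed before the data were examined: stem cell associated, MAPK feedback targets, primed progenitor, spermatogonial differentiation, meiotic prophase, retinoic acid pathway, DNA replication, mitosis, G1 cyclins and CDK inhibitors, telomerase and shelterin, piRNA pathway, DNA methylation machinery, Polycomb and histone methylation, pluripotency and germ cell identity, imprinted genes, Wnt receptors and targets, Notch pathway, adhesion and homing, glycolysis, oxidative phosphorylation, ribosomal proteins, dissociation and heat stress, and markers of Sertoli cells, Leydig cells, peritubular myoid cells and fibroblasts, macrophages and leukocytes, endothelium, red blood cells, spermatocytes and spermatids. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists, with the estimated correlation and fry beside it, and sort genes were left out of the lists where the gates differed on them. A list score is the mean log2(CPM + 1) of its members. Genes named were, by a rule also fixed before, the 4 sort genes, the 10 largest rises and falls per comparison among genes past the threshold with a mean of at least 20 CPM in a group and no overlap between the groups' libraries, and up to 4 members per list with the smallest adjusted p, with some members that did not pass. Chance alone would part 4 libraries from 4 in 2.86% of genes and 5 from 4 in 1.59%.

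The alternatives fixed before were RLE and upper-quartile scaling, no count filter, a filter of 1 CPM in 4 libraries, DESeq2 1.42.0, limma voom with and without sample quality weights, a fold threshold of 1.5 (glmTreat), a fit of only the 2 groups, the replicate number as a block, and each replicate left out in turn. On simulated data with 200 changed genes the edgeR step recovered 77.3% of 66 genes changed 4-fold and 37.3% of 67 changed 2-fold between GFRA1pos and GFRA1neg, over 15189 genes, with 8 of 87 calls on unchanged genes. For KITpos minus GFRA1neg, over 15160 genes, it recovered 81.8% and 40.3%, and for P6gonocyte minus GFRA1pos, over 15274 genes, 75.8% and 29.9%. Changes of 1.5-fold were recovered in 2.99%, 4.48% and 11.9% of 67 genes in these comparisons. In the data 14.1%, 45.1% and 39.2% of genes were called, far more than were changed in the simulation. The adjustment is stricter when few genes change, so these rates may not carry over to the data. Figures were drawn with matplotlib 3.10.9.

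Further alternatives were chosen only after the data were seen: leaving out the 4 libraries highest in spermatid transcripts, leaving out the 2 most abundant rows, leaving out 1268 genes that followed the spermatid score at a correlation of 0.7 or more, and fitting that score as a covariate. In all 32 alternatives were run. Some steps were changed after a result was seen. In the test of transcript length and GC content, rounding to 2 decimals was added when the ribosomal bound was met only in the third decimal, and the outcome is read as undecided. The test of Sertoli markers first used the correlation of markers over the 4 P6gonocyte libraries and was replaced by a count of peaks, because 4 libraries are too few for a correlation, and a test of Leydig markers over 5 KITpos libraries was dropped for the same reason. The search for libraries that stand apart first used list scores without TMM scaling and then the scores of the report. Reads, alignment and any genome coordinates were left out, since only counts were analysed here.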

Results

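Gene counts were measured by RNA sequencing in 17 libraries of germ cells sorted from mouse testis, in 4 groups. From adult Tert-Tomato reporter mice came GFRA1-positive, TERT-high, Kit-negative cells (GFRA1pos, n = 4), GFRA1-negative, TERT-high, Kit-negative cells (GFRA1neg, n = 4) and TERT-high, Kit-positive cells (KITpos, n = 5). From mice at postnatal day 6 came gonocytes positive for TERT and an OCT4-GFP reporter (P6gonocyte, n = 4). The labels do not say whether libraries of one group came from separate animals, so the p-values measure a spread between samples that may be technical. Total counts ran from 10918223 to 11567191 in GFRA1pos, from 9965437 to 12641907 in GFRA1neg, from 5178352 to 8300165 in KITpos and from 6479216 to 8468203 in P6gonocyte. A single row without a matched symbol held 26.7% ± 3.0 (SD, n = 4) of the counts in GFRA1pos and 12% ± 2.2 (SD, n = 4) in P6gonocyte. The mean share of that row was 27.3% in GFRA1neg and 20.8% in KITpos. The gene with the next largest share, Lars2, held 3.81% in GFRA1pos, 4.41% in GFRA1neg, 1.44% in KITpos and 1.13% in P6gonocyte. A transcript absent from all libraries of a group could have stood at up to 0.069 CPM (counts scaled to a common library size) in GFRA1pos, 0.072 in GFRA1neg, 0.085 in KITpos and 0.092 in P6gonocyte, where 3 counts over the group set the floor. Floors cover counting error only, since PCR reads without molecular identifiers are not independent molecules.

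Transcripts of the sorted markers were compared across the groups first. Gfra1, which encodes a receptor for the niche factor GDNF, had 390 CPM ± 28.9 (SD, n = 4) in GFRA1pos and 22.8 ± 3.3 (SD, n = 4) in GFRA1neg. It had 4.71 CPM ± 2.6 (SD, n = 5) in KITpos and 145 ± 18.3 (SD, n = 4) in P6gonocyte. Kit, the receptor for stem cell factor, had 353 CPM ± 76.3 (SD, n = 5) in KITpos, 17.6 ± 3.8 (SD, n = 4) in GFRA1pos and 27.6 ± 14.7 (SD, n = 4) in GFRA1neg. P6gonocyte libraries had 188 CPM of Kit ± 29.4 (SD, n = 4). Tert was low in every group, with means of 7.25 CPM in GFRA1pos, 11.3 in GFRA1neg, 7.54 in KITpos and 7.21 in P6gonocyte. Pou5f1, the gene of the OCT4 reporter, had 19.7 CPM ± 9.6 (SD, n = 4) in P6gonocyte and means of 3.09, 4.28 and 0.837 in GFRA1pos, GFRA1neg and KITpos. In replicate 2 of P6gonocyte Pou5f1 stood at 5.53 CPM, against 23.0 CPM or more in the other libraries of that group. On the first 2 principal components, with 41.0% and 26.2% of the variance, KITpos and P6gonocyte libraries lay apart, and GFRA1pos and GFRA1neg libraries overlapped.

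**Figure D1:**
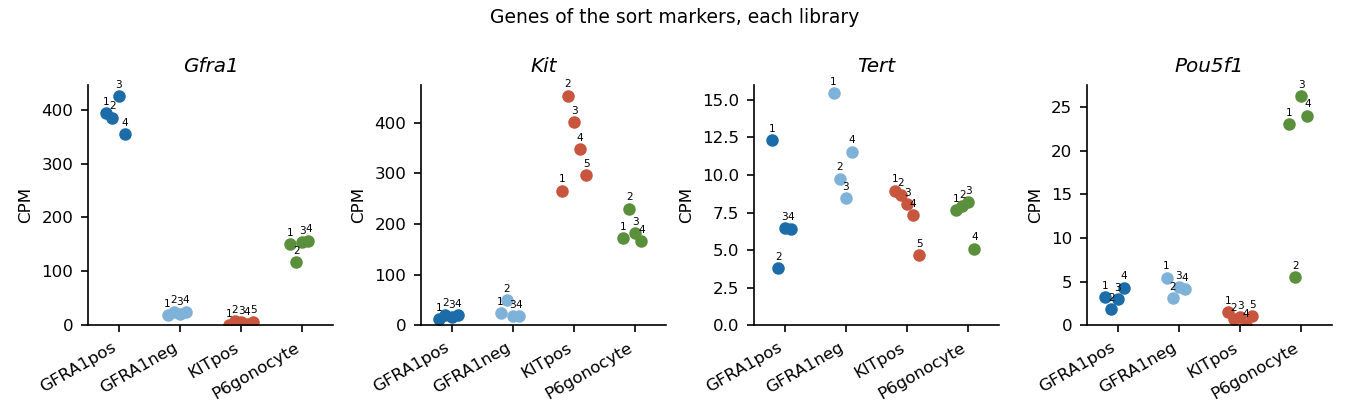
CPM of the genes of the 4 sort markers in each library, with the replicate number beside each point. Gfra1 was highest in GFRA1pos (355 to 426 CPM), Kit in KITpos (266 to 453 CPM) and Pou5f1 in P6gonocyte (5.53 to 26.3 CPM).

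**Figure D2:**
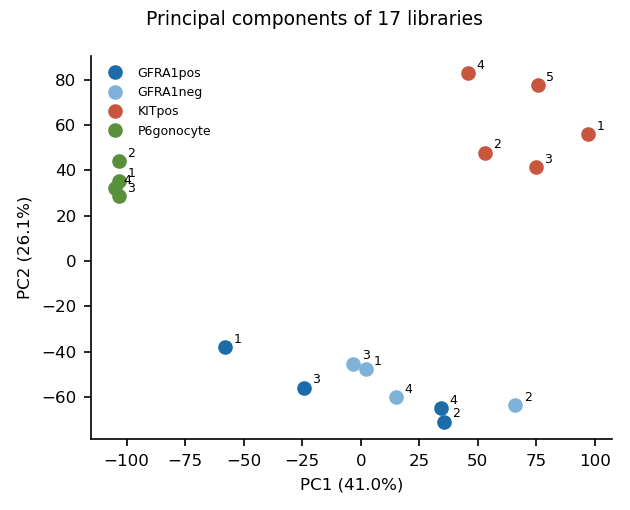
First and second principal components of the 17 libraries, coloured by group, with the replicate number beside each point. The axes hold 41.0% and 26.2% of the variance.

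GFRA1pos was compared with GFRA1neg to ask which transcripts separate the TERT-high, Kit-negative cells that carry the GDNF receptor from those that do not. Nefm (Entrez 18040) was 37.4-fold higher in GFRA1pos, at 57.0 CPM ± 1.6 (SD, n = 4) against 1.5 ± 0.92 (SD, n = 4). Egr2 (Entrez 13654), an early response transcription factor, was 19.7-fold higher, at 216 CPM against 11. Eomes (Entrez 13813) was 18.1-fold higher, with 27.2 CPM in GFRA1pos and 1.49 in GFRA1neg. In the other direction, Neurog3 (Entrez 11925), a transcription factor of progenitor spermatogonia, was 7.7-fold lower in GFRA1pos, at 5.08 CPM against 39.3. Cxcl12 (Entrez 20315) was 20.6-fold lower, at 2.05 CPM against 42.5.

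By the edgeR quasi-likelihood test, 1128 of 15451 genes were higher and 1057 lower in GFRA1pos at an adjusted p under 0.05, of which 600 and 490 changed over 2-fold. The 10 largest named rises also held Hs3st3b1 (28.1-fold), Mpzl2 (22.9-fold), Tmc8 (22.2-fold), Zic1 (21.9-fold), Sez6 (19.7-fold), Tmem132e (19.1-fold) and the sort gene Gfra1 (17.1-fold). The largest named falls also held Mobp (36.8-fold), Six4 (9.8-fold), Epb41l4a (8.6-fold), Nr2e1 (8.2-fold), Tmem63c (8.0-fold), Onecut2 (7.4-fold), Ddit4 (7.2-fold) and Cmklr1 (6.7-fold). Egr2 had a log2 fold change of 4.30 ± 0.23 (SE) and an edgeR adjusted p of 1.2e-09. By the rule of choice, libraries of the 2 groups did not overlap for these genes, which chance gives in 2.86% of genes.

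Of 21 measured stem cell associated genes other than Gfra1, 18 rose and none fell (18 and 1 adjusted over the list alone), with a median log2 fold change of 2.86. Mcam rose by 2.18 ± 0.16 (SE) and Etv5 by 3.67 ± 0.33 on the log2 scale. Zbtb16 at a log2 fold change of -0.48 (edgeR adjusted p = 0.13) and Pax7 at -0.95 (edgeR adjusted p = 0.38) were among the members that did not pass; both passed when only the libraries of the 2 groups were fitted, at 0.034 and 0.036, and by limma voom with sample quality weights, at 0.015 and 0.036. Of 18 MAPK feedback targets, 17 rose, including Dusp6 (3.63 ± 0.30), Dusp4 (2.87 ± 0.34) and Ccnd1 (1.24 ± 0.12), with 17 adjusted over the list alone and a median of 2.15. Of 15 primed progenitor genes, 8 fell and none rose, with 9 lower adjusted over the list alone. Rarg fell by 2.36 ± 0.23, Lin28a by 1.18 ± 0.15 and Upp1 by 2.39 ± 0.35. DNA replication genes rose in 26 of 40 cases (28 adjusted over the list alone), among them Prim1 (1.60 ± 0.16), Rrm2 (1.75 ± 0.21) and Mcm10 (0.99 ± 0.12). Mitosis genes rose in 14 of 30 cases (17 adjusted over the list alone), with Cenpa at 1.18 ± 0.14 and Ccnb1 at 0.85 ± 0.12. Of 20 piRNA pathway genes, 10 fell (11 adjusted over the list alone), including Tdrd9 (-0.94 ± 0.15) and Tdrd5 (-0.79 ± 0.14). Adhesion and homing genes rose in 15 and fell in 3 of 25 cases (16 and 3 adjusted over the list alone), with Cdh3 at 2.17 ± 0.22, Epcam at 1.56 ± 0.16, Itgav at 2.47 ± 0.27 and Itga3 at 2.33 ± 0.28.

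The camera test with a preset correlation called 12 of the 30 lists in this comparison, 7 up and 5 down. With an estimated correlation 7 of them held, which were the stem cell associated, MAPK feedback, primed progenitor, DNA replication, mitosis, piRNA and adhesion lists. Meiotic prophase genes fell in 7 of 29 cases (10 adjusted over the list alone), led by Meioc (-1.85 ± 0.32) and Sycp3 (-1.67 ± 0.38), and that list had adjusted p = 0.41 with an estimated correlation. Imprinted genes rose in 6 and fell in 4 of 24 cases (8 and 4 adjusted over the list alone), with H19 at 2.14 ± 0.16, Mest at 1.62 ± 0.14 and Peg10 at -1.71 ± 0.19; the list had adjusted p = 0.17 with an estimated correlation, and 0.083 without GFRA1neg replicate 2. The dissociation and heat stress list had 6 higher and 2 lower of 20 genes (7 and 2 adjusted over the list alone), with Fos at 2.78 ± 0.34 and Hspa1a at -2.35 ± 0.38; the list had adjusted p = 0.18 with an estimated correlation, and 0.057 without GFRA1pos replicate 3. Pluripotency genes fell in 5 of 17 cases (5 adjusted over the list alone), including Dppa3 (-3.76 ± 0.63, and -4.69 without GFRA1pos replicate 1) and Tfap2c (-2.31 ± 0.40), at a list median of -0.01 and adjusted p = 0.23 with an estimated correlation. That list was not called without GFRA1pos replicate 2 (0.11), 3 (0.062) or 4 (0.058), or without GFRA1neg replicate 1 (0.075) or 4 (0.059). Ribosomal protein genes rose in 1 and fell in 2 of 81 cases (1 and 0 adjusted over the list alone), with a median of -0.22 and adjusted p = 0.89 with an estimated correlation; the list was not called without GFRA1neg replicate 4 (0.42), GFRA1pos replicate 3 (0.11) or GFRA1pos replicate 4 (0.068).

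The remaining lists were not called in this comparison. Differentiation genes rose in 3 and fell in 6 of 17 cases (3 and 7 adjusted over the list alone), where Ccnd2 (2.24 ± 0.17) and Stra8 (1.24 ± 0.23) rose and Dnmt3a (-0.84 ± 0.15) fell. Among DNA methylation genes, with 3 higher and 4 lower of 18 (3 and 5 adjusted over the list alone), Uhrf1 (1.11 ± 0.13) and Dnmt1 (0.91 ± 0.16) rose and Tet3 (-2.01 ± 0.17) fell. In the Polycomb list, with 3 higher and 4 lower of 29 (3 and 4 adjusted over the list alone), Scmh1 (1.46 ± 0.17) and Phf19 (2.42 ± 0.42) rose and Ehmt2 (-1.41 ± 0.17) fell. Notch1 (2.18 ± 0.22) and Dll4 (4.93 ± 0.60) rose in the Notch list, with 4 higher and 2 lower of 21 (5 and 3 adjusted over the list alone). In the Wnt list, with 6 higher and 1 lower of 32 (6 and 1 adjusted over the list alone), Wif1 (4.91 ± 0.80, and 5.82 without GFRA1neg replicate 4) and Fzd10 (2.27 ± 0.42) rose and Lef1 (-1.36 ± 0.26) fell. The list of G1 cyclins and CDK inhibitors had 3 higher and 3 lower of 16 (3 and 3 adjusted over the list alone), where Cdk6 fell by 2.20 ± 0.13 and Ccnd2 and Ccnd1 rose. Of 16 retinoic acid genes, 2 rose and 1 fell (2 and 1 adjusted over the list alone): Aldh1a3 (5.11 ± 0.63, and 5.79 without GFRA1neg replicate 4) and Dhrs3 (2.04 ± 0.42) rose and Rarg fell. The oxidative phosphorylation, glycolysis and telomerase lists had medians of 0.02, 0.03 and 0.04 (log2). Among markers of other cells, 2 of 5 macrophage markers rose and none fell (2 and 0 adjusted over the list alone), with Mrc1 at 3.02 ± 0.62 (4.42 without GFRA1neg replicate 2) and a fry adjusted p of 0.00066 for change on balance one way. Of 8 endothelial markers 2 rose and none fell (2 and 0 adjusted over the list alone), with Kdr at 2.65 ± 0.52 and a fry adjusted p of 0.00068. The Sertoli and spermatocyte lists each had 0 higher and 2 lower of 16, the myoid list 0 and 1 of 12, and the Leydig, red blood cell and spermatid lists had 0 called genes. Median and mean differed in sign in the retinoic acid, telomerase, Polycomb, Notch and glycolysis lists, and the test differed from both in the Leydig list.

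KITpos was compared with GFRA1neg to ask what changes when TERT-high cells gain Kit. Stra8 (Entrez 20899), a retinoic acid responsive gene, was 25.0-fold higher in KITpos, at 249 CPM ± 59.5 (SD, n = 5) against 9.91 ± 0.92 (SD, n = 4). Cited1 (Entrez 12705) was 27.8-fold higher, at 122 CPM against 4.34. Ptch1 (Entrez 19206), a hedgehog receptor, was 86.8-fold lower, at 3.45 CPM ± 2.0 (SD, n = 5) against 312 ± 48.5 (SD, n = 4). Cdkn1b (Entrez 12576), a CDK inhibitor, was 52.4-fold lower, at 0.441 CPM against 23.3.

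A total of 3419 genes were higher and 3550 lower in KITpos by the edgeR test, and 1637 and 2021 of them changed over 2-fold. The largest named rises also held Fgf11 (19.4-fold), H2bc14 (17.3-fold), H2ac1 (14.3-fold), the sort gene Kit (12.7-fold), Cd63 (12.4-fold), Selenom (11.6-fold) and Ass1 (11.1-fold). H2bc14 and H2ac1 belong to histone families of near-identical genes, so their counts are uncertain. The largest named falls also held Gbp2 (170-fold, with 6 counts in KITpos), Mir6236 (117-fold), Six4 (88.9-fold), Nr2e1 (70.6-fold), Havcr1 (59.6-fold), Tbx20 (58.6-fold), Arhgef15 (55.8-fold) and Enc1 (54.3-fold). Mir6236 did not pass by limma voom, at an adjusted p of 0.052 and, with sample quality weights, 0.12. Its log2 fold change of -6.87 was -6.11 without GFRA1neg replicate 1, and that of Gbp2, -7.41, was -9.22 without KITpos replicate 2.

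Of 16 differentiation genes other than Kit, 11 rose and 2 fell in KITpos (12 and 2 adjusted over the list alone), with Rhox13 at 2.81 ± 0.22 (SE), Crabp1 at 2.51 ± 0.23 and Ccna2 at 1.62 ± 0.12 on the log2 scale. That list had adjusted p = 0.075 with an estimated correlation. Primed progenitor genes fell in 12 and rose in 2 of 15 cases (13 and 2 adjusted over the list alone), including Lin28a (-2.92 ± 0.15), Glis3 (-4.01 ± 0.20) and Nanos3 (-3.21 ± 0.29), while Ddx4 at -0.33 (edgeR adjusted p = 0.09) did not pass. Stem cell associated genes fell in 11 and rose in 1 of 21 cases (12 and 1 adjusted over the list alone), with Ret at -4.50 ± 0.25 and Zbtb16 at -3.36 ± 0.20, and the list had adjusted p = 0.10 with an estimated correlation. MAPK feedback targets fell in 8 and rose in 1 of 18 cases (8 and 1 adjusted over the list alone), where Il17rd fell by 3.02 ± 0.20 and Ccnd1 rose by 1.63 ± 0.12; the list had adjusted p = 0.29 with an estimated correlation, and 0.052 by limma voom. DNA replication genes rose in 33 and fell in 3 of 40 cases (33 and 3 adjusted over the list alone), led by Pcna (1.83 ± 0.14), at adjusted p = 0.075 with an estimated correlation. Mitosis genes rose in 22 and fell in 1 of 30 cases (23 and 1 adjusted over the list alone), with Cenpa at 1.77 ± 0.14 and Tpx2 at 1.17 ± 0.11. Meiotic prophase genes rose in 16 of 29 cases (16 higher and 1 lower adjusted over the list alone), with Prdm9 at 3.34 ± 0.35 and Tex11 at 1.58 ± 0.18, at adjusted p = 0.29 with an estimated correlation. Of 13 lists called with the preset correlation, the primed progenitor and mitosis lists held with an estimated correlation.

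Ribosomal protein genes rose in 64 and fell in 3 of 81 cases (67 and 3 adjusted over the list alone), with a median log2 fold change of 1.00 and adjusted p = 0.30 with an estimated correlation. Rpl39 (3.26 ± 0.24), Rps27l (2.45 ± 0.21) and Rpl13 (1.78 ± 0.18) were among those that rose. Oxidative phosphorylation genes rose in 58 and fell in 1 of 81 cases (60 and 2 adjusted over the list alone), with a median of 0.98 and adjusted p = 0.29 with an estimated correlation. Examples were Uqcr11 (2.18 ± 0.18), Ndufa11 (2.23 ± 0.19) and Atp5k (2.54 ± 0.23). Glycolysis genes fell in 10 and rose in 2 of 19 cases (10 and 2 adjusted over the list alone), with Slc2a1 at -2.81 ± 0.19 and Pkm at -1.90 ± 0.15, and adjusted p = 0.29 with an estimated correlation. Of the piRNA genes 8 fell and 2 rose (8 and 2 adjusted over the list alone), led by Tdrd5 (-2.00 ± 0.14) and Piwil4 (-2.76 ± 0.23), at adjusted p = 0.20 with an estimated correlation. Pluripotency genes fell in 9 and rose in 3 of 16 cases (9 and 3 adjusted over the list alone), with Sall4 at -1.79 ± 0.23; the list had adjusted p = 0.19 with an estimated correlation, and 0.052 by limma voom. Dissociation and heat stress genes fell in 10 and rose in 4 of 20 cases (11 and 4 adjusted over the list alone), with Egr1 at -4.25 ± 0.18 and Gadd45b at 3.05 ± 0.44, at adjusted p = 0.19 with an estimated correlation. Median and test differed in sign in the G1 cyclin, Polycomb and spermatid lists, and the mean of the myoid list was positive beside a negative median and test.

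Markers of Leydig cells, which make androgens between the tubules, rose in 7 of 11 cases in KITpos (7 adjusted over the list alone). Cyp17a1 had 10.1 CPM ± 5.9 (SD, n = 5) against 1.51 ± 1.2 (SD, n = 4), and Akr1cl rose by 4.92 ± 1.04 (log2). Cyp11a1 and Hsd17b3 passed with all libraries but not without KITpos replicate 1, at adjusted p of 0.057 and 0.071. Star, at a log2 fold change of 0.46 (edgeR adjusted p = 0.15), did not pass. The list itself was not called, at an adjusted p of 0.052 by camera, with adjusted p = 0.57 with an estimated correlation. Over the alternatives it ranged from 0.0099 to 0.57 and was under 0.05 in 11. Without GFRA1neg replicate 2 the log2 fold change of Akr1cl was 8.07, of Cyp17a1 3.43, of Cyp11a1 6.03 and of Hsd17b3 6.08, and without KITpos replicate 1 that of Cyp11a1 was 2.58 and of Hsd17b3 2.29. Other somatic markers moved as well, in lists that were not called. Sertoli markers rose in 7 and fell in 2 of 16 cases (7 and 2 adjusted over the list alone), with a median of 0.80, Aard at 1.71 ± 0.44 and Trf at -3.62 ± 0.36 (-4.22 without KITpos replicate 2). Of 8 endothelial markers 4 fell and 1 rose (5 and 1 adjusted over the list alone), with Pecam1 at -3.61 ± 0.54 and Egfl7 at 1.25 ± 0.34. The myoid list had 1 higher and 1 lower of 12, the macrophage list 0 and 1 of 5, the spermatocyte list 0 and 1 of 16, and the spermatid and red blood cell lists had 0 called genes. By limma voom Aard did not pass here, at 0.052.

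P6gonocyte was compared with GFRA1pos to ask how postnatal germ cells differ from adult GFRA1-positive cells. GFRA1pos cells were sorted for GFRA1 and against Kit, while the P6gonocyte titles name only TERT and OCT4-GFP. Age and the sort therefore differ together, and cannot be told apart for any gene or list in this comparison. Aldh1a1 (Entrez 11668), which makes retinoic acid, was 32.3-fold higher, at 59.1 CPM ± 43.7 (SD, n = 4) against 1.83 ± 0.99 (SD, n = 4), and without P6gonocyte replicate 2 its log2 fold change was 4.35 in place of 5.01. Prm1 (Entrez 19118), which packs sperm DNA, had 201 CPM ± 217 (SD, n = 4) in GFRA1pos and 0 counts in the 4 P6gonocyte libraries, so it was at least 2170-fold lower, and at least 1090-fold without GFRA1pos replicate 2. The pluripotency and germ cell identity list was not called, with 4 higher and 3 lower of 15 (4 and 3 adjusted over the list alone) and a median log2 fold change of -0.17. In it Dazl, a germ cell RNA-binding protein, rose by 1.72 ± 0.17 (SE) and Dppa3 by 2.91 ± 0.63 (3.85 without GFRA1pos replicate 1), and Sall4 fell by 1.04 ± 0.24. The sort gene Kit was 10.6-fold higher. GFRA1pos cells were gated as Kit-negative, so the gate and a difference between the cells cannot be told apart.

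In P6gonocyte 2679 genes were higher and 3381 lower by the edgeR test, and 761 and 2260 of them changed over 2-fold. The largest named rises also held Aard (19.4-fold), Gstm2 (14.6-fold), Sparc (12.5-fold), Cxcl12 (10.9-fold), Clu (8.2-fold), Hmgn5 (6.8-fold), Serpine2 (4.8-fold) and Gstm1 (4.7-fold). Replicate 2 of P6gonocyte stood above the other libraries of its group in Aldh1a1 (122 CPM), Sparc (127), Clu (83.1) and Aard (74.7). Without that library the log2 fold changes were 3.62 for Aard, 3.24 for Gstm2, 2.31 for Clu and 1.60 for Gstm1, against 4.28, 3.87, 3.04 and 2.23 with it. Among the largest falls, genes with 0 counts in P6gonocyte were lower by at least 1030-fold for Prr30, 709-fold for Smcp, 620-fold for Cabs1, 503-fold for Actl11, 445-fold for Morc2b, 374-fold for Hils1, 309-fold for Cby2 and 296-fold for Ubqlnl. Without GFRA1pos replicate 2 these bounds were 612 for Prr30, 417 for Smcp, 301 for Cabs1, 293 for Actl11, 224 for Hils1, 157 for Cby2 and 179 for Ubqlnl, and without replicate 4 that of Morc2b was 298. By limma voom Prm1, Prr30, Smcp, Cabs1, Actl11 and Cby2 did not pass, at adjusted p from 0.052 for Cby2 to 0.10 for Smcp.

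The 18 spermatid markers all fell in P6gonocyte (18 adjusted over the list alone), with a median log2 fold change of -6.63, which was the same with the 3 members at 0 set to their bound. Akap4 fell by 7.11 ± 0.88, and by 6.43 without GFRA1pos replicate 2. The list had adjusted p = 0.21 with an estimated correlation. Spermatocyte markers fell in 12 of 16 cases (12 adjusted over the list alone), including Ldhc (-6.44 ± 0.87) and Nme5 (-3.38 ± 0.54), at adjusted p = 0.28 with an estimated correlation. The mean level of spermatid markers, as log2(CPM + 1), ran from 2.64 to 6.31 in GFRA1pos, from 4.42 to 6.39 in GFRA1neg, from 4.25 to 5.97 in KITpos and from 0.72 to 0.91 in P6gonocyte. Sertoli cell markers rose in 13 of 16 cases (13 adjusted over the list alone), led by Aard and Clu, with Cst9 at 4.48 ± 0.81 and Mro at 4.39 ± 0.81. Without P6gonocyte replicate 2 these were 3.67 and 3.59, and without GFRA1pos replicate 2 Cst9 was at 5.48. Wt1 at 0.96 (edgeR adjusted p = 0.20) did not pass, and the list had adjusted p = 0.20 with an estimated correlation.

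Stem cell associated genes fell in 12 of 21 cases (13 adjusted over the list alone), with Mcam at -1.14 ± 0.15, Pdx1 at -6.29 ± 0.88 (-9.23 without P6gonocyte replicate 2) and Eomes at -2.39 ± 0.35, and adjusted p = 0.18 with an estimated correlation. Nanos2 at -1.15 (edgeR adjusted p = 0.067) did not pass, and passed in 6 alternative fits, by DESeq2 at 0.0084. MAPK feedback targets fell in 14 and rose in 1 of 18 cases (14 and 1 adjusted over the list alone), including Egr2 (-1.62 ± 0.20) and Spry2 (-2.06 ± 0.33), at adjusted p = 0.21 with an estimated correlation. Differentiation genes rose in 12 and fell in 1 of 16 cases (12 and 1 adjusted over the list alone), with Stra8 at 1.65 ± 0.22 and Dnmt3b at 0.98 ± 0.16, at adjusted p = 0.16 with an estimated correlation. DNA replication genes rose in 21 and fell in 1 of 40 cases (23 and 1 adjusted over the list alone), with Mcm4 at 1.02 ± 0.12, and adjusted p = 0.21 with an estimated correlation. Mitosis genes rose in 14 and fell in 1 of 30 cases (14 and 1 adjusted over the list alone), with Ndc80 at 1.07 ± 0.18, and adjusted p = 0.16 with an estimated correlation. Ribosomal protein genes rose in 42 of 81 cases (45 adjusted over the list alone), with Rpl7a at 1.10 ± 0.15, and adjusted p = 0.58 with an estimated correlation. Oxidative phosphorylation genes rose in 26 and fell in 3 of 81 cases (25 and 3 adjusted over the list alone), with Atp5a1 at 0.96 ± 0.12, and adjusted p = 0.59 with an estimated correlation. Dissociation and heat stress genes fell in 8 and rose in 1 of 20 cases (8 and 1 adjusted over the list alone), with Zfp36 at -2.74 ± 0.23, and adjusted p = 0.18 with an estimated correlation. Of the 11 lists called with the preset correlation, 0 held with an estimated correlation, at which 6 of the 30 lists had an unadjusted p under 0.05.

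Among lists not called in P6gonocyte, Hells (1.71 ± 0.18) and Tdg (0.96 ± 0.18) rose in the DNA methylation list, with 6 higher and 2 lower of 18 (6 and 2 adjusted over the list alone). The piRNA list had 5 higher and 4 lower of 20 (5 and 4 adjusted over the list alone) and a median of -0.07, where Tdrkh (1.15 ± 0.16) and Asz1 (0.85 ± 0.15) rose and Tdrd6 (-4.89 ± 0.88) fell. Without GFRA1pos replicate 4 Tdrd6 was at -4.27, and by limma voom it did not pass, at 0.066. Dkc1 (2.12 ± 0.21) rose in the telomerase list, with 5 higher and 0 lower of 15 (3 and 0 adjusted over the list alone). The imprinted list had 4 higher and 4 lower of 24 (4 and 4 adjusted over the list alone) and a median of 0.32, where H19 (-2.11 ± 0.16) and Igf2 (-1.44 ± 0.23) fell and Mest (0.63 ± 0.13) rose. The peritubular myoid and fibroblast markers had 5 higher and 2 lower of 12, and the Leydig markers 3 higher and 1 lower of 11. The macrophage markers had 2 lower of 5 and the endothelial markers 2 lower of 8. Of the red blood cell markers only Alas2 was tested, with 1.42 ± 0.47 (log2); it lost its call without GFRA1pos replicate 2 (0.064) or 4 (0.050), or P6gonocyte replicate 3 (0.059) or 4 (0.10). Median and test differed in sign in the retinoic acid, G1 cyclin, piRNA, pluripotency, glycolysis and Leydig lists, and the mean differed from both in the Polycomb list. By fry, which asks whether the genes of a list move on balance one way and does not compare them with other genes, 16, 22 and 19 of the 30 lists passed in the 3 comparisons. Its mixed test, for change in either direction, passed 25, 26 and 29.

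**Figure D3:**
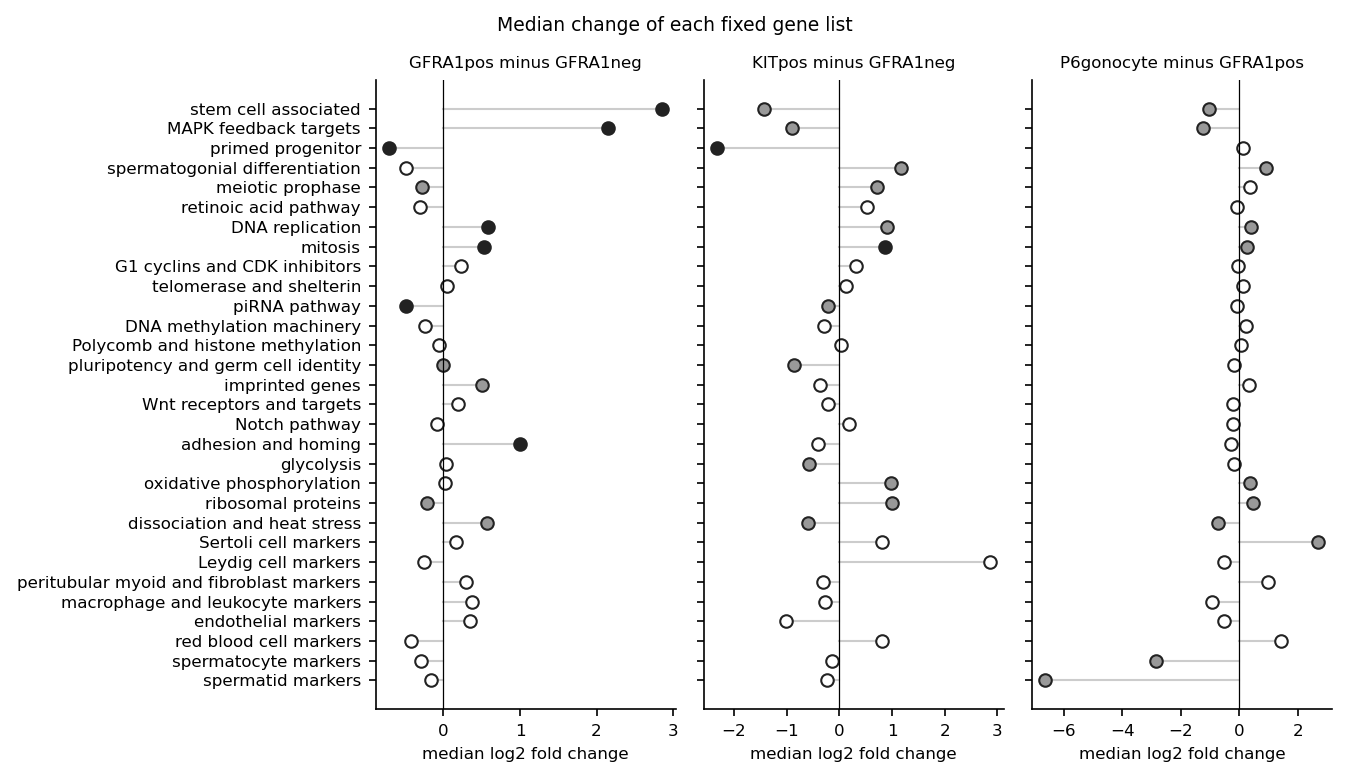
Median log2 fold change of each fixed gene list in the 3 comparisons, with black points for lists called by camera with both the preset and the estimated correlation, grey for the preset alone and white for neither. The spermatid list had the lowest median, -6.63, in P6gonocyte minus GFRA1pos.

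**Figure D4:**
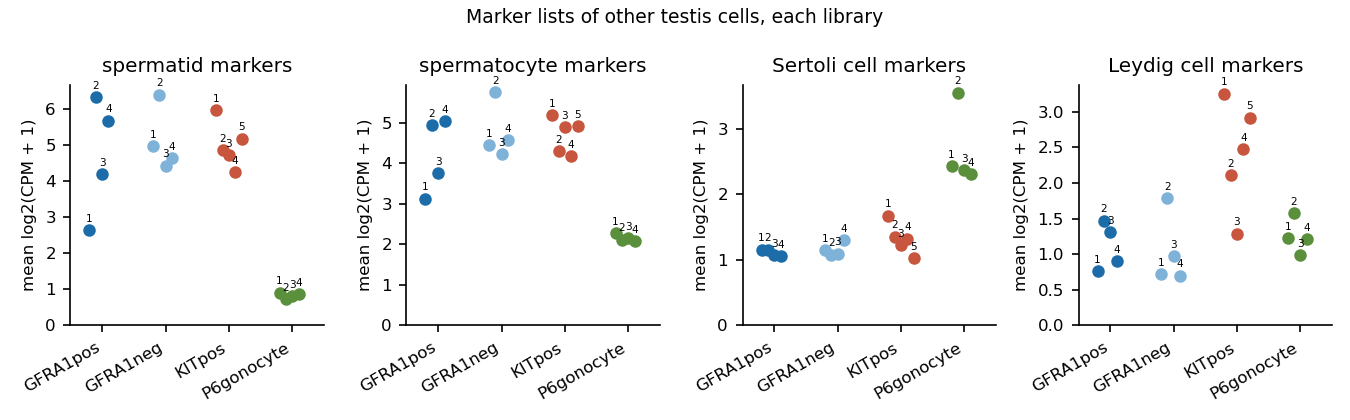
Mean log2(CPM + 1) of 4 marker lists in each library, by group, with the replicate number beside each point. The spermatid score lay at 0.91 or less in P6gonocyte and at 2.64 or more in the adult libraries, and the Sertoli score was highest in P6gonocyte replicate 2, at 3.55.

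KITpos had 3844 genes higher and 3663 lower than GFRA1pos, and P6gonocyte had 2899 higher and 3842 lower than GFRA1neg, by the same edgeR test. Across both adult steps, 388 genes were higher in GFRA1pos and in KITpos than in GFRA1neg, where independent lists would share 250. In both, 565 genes were lower, where independent lists would share 243. Another 298 were higher in GFRA1pos and lower in KITpos (259 for independent lists), and 132 were lower in GFRA1pos and higher in KITpos (234). These comparisons share the GFRA1neg libraries. With the GFRA1neg libraries split 2 and 2 the median overlaps were 174, 293, 163 and 63, where independent lists would share means of 110, 106, 121 and 97. The log2 fold changes of the 2 steps had a covariance across genes of 0.187, against 0.087 in simulated unchanged groups, and 0.058 to 0.184 over the 6 assignments of split libraries. Their correlation was 0.216, against 0.517 simulated. The simulated groups hold no real changes, which can widen the spread of fold changes and lower a correlation. Only the covariances can therefore be compared. Genes are not independent replicates.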

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

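The rule for finding libraries that stand apart was set before the values were compared, but the tests of spermatid RNA, Sertoli RNA, the 2 most abundant rows and the splits of libraries were chosen only after the results were seen, and the test of length and GC content was written beforehand and its rounding changed afterwards. In 248 groups of values, 20 held a library apart from its group, where chance gives 12.4. P6gonocyte replicate 2 stood apart in the scores of differentiation (6.27), retinoic acid (3.34), glycolysis (5.79) and Sertoli markers (3.55, next 2.43). It also stood apart in Gfra1 (118 CPM), Pou5f1 (5.53), Aldh1a1 (122), Aard (74.7), Gstm2 (55.3), Sparc (127), Clu (83.1) and Gstm1 (223). GFRA1pos replicate 4 was low in DNA replication (6.00) and DNA methylation (5.02) scores, and KITpos replicate 1 was low in DNA methylation (5.09) and high in red blood cell markers (1.81). Endothelial scores stood apart in GFRA1pos replicate 3 (1.81) and GFRA1neg replicate 4 (1.78), H2ac1 in GFRA1neg replicate 4 (28.5 CPM) and Gbp2 in KITpos replicate 2 (0.577 CPM).

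Spermatid transcripts, low in P6gonocyte, may come from spermatid RNA in the adult libraries, and 17 of 18 markers followed the others over the adult libraries. Prm1 had 201 CPM ± 217 (SD, n = 4) in GFRA1pos, Prm2 207 ± 205 and Akap4 130 ± 117. The sort for TERT-high, Kit-negative cells would remove spermatids if they hold no reporter. None of the list's genes is in another list, and all 18 had at least 1 CPM in GFRA1pos, GFRA1neg and KITpos. Of 3363 lower genes outside the list, 2061 (61.3%) had a slope on the spermatid score with an upper limit under 0.5. Among other tested genes 93.0% did. Another 252 lower genes (7.49%) had a lower limit over 0.5, against 0.124%, so spermatid RNA may account for a part of the lower genes. Slopes under 0.5 argue against RNA wholly from spermatids, in genes well above the 1 CPM added before the log. They cannot exclude a smaller spermatid share in genes that germ cells also express, so how far it reaches was left open. Spermatocyte markers also fell in P6gonocyte, in 12 of 16 cases, and slopes on their score were not tested.

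Ribosomal protein and oxidative phosphorylation transcripts, higher in KITpos, have short transcripts, with median lengths of 1059 and 1001 against 3220 for all genes. The list tests had adjusted p = 0.30 and 0.29 with an estimated correlation. Genes of like length and GC content had medians of 0.26 and 0.32, with upper limits over the draws of 0.50 and 0.57, beside list medians of 1.00 and 0.98. Of 1000 draws, 0 came as high for either list. The upper limits had to lie under 0.50 and 0.49, after rounding to 2 decimals, and did not, so the outcome was undecided. The draws also treat genes as independent, while the lists had estimated correlations of 0.73 and 0.51. How much of the rise length and GC content account for was left open. Without the 2 most abundant rows the medians were 0.95 and 0.92, and the median of all genes moved from 0.032 to -0.035. TMM scaling already limits the weight of such rows, so the lists could hardly have lost their rise here. The rise did not need the counts of those rows, but a cause that their differing share reflects was not tested.

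Sertoli markers were higher in P6gonocyte, in replicate 2 above all (score 3.55), but also in replicates 1, 3 and 4 (2.43, 2.37 and 2.30), against 1.05 to 1.15 in GFRA1pos. In replicate 2, 16 of 16 measured markers peaked, where 1000 random sets of genes had a highest count of 12; this largely restates that the score of that library stood apart, so it does not tell Sertoli RNA from another source. Without replicate 2 the Sertoli cell markers list in P6gonocyte minus GFRA1pos was still called by camera, at an adjusted p of 9.1e-06. RNA in 1 library is therefore not enough for the rise, and its source was left open. With all libraries and an estimated correlation the list had an adjusted p of 0.20. Clu had 38.6 CPM ± 30.8 (SD, n = 4) and Aard 36.2 ± 26.7 in P6gonocyte, none of the 19 markers is in another list, and 18 had at least 1 CPM there. The sort for cells with both the TERT and OCT4-GFP reporters would remove Sertoli cells if they lack either reporter, but its purity was not measured here.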

How the results depend on the processing

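Alternatives without spermatid-rich libraries, without the 2 most abundant rows, without genes that track the spermatid score and with that score as a covariate were chosen only after the results were seen. The cause of a changed count was not tested unless stated. A fold threshold of 1.5 gave 382 higher and 238 lower genes in GFRA1pos against GFRA1neg, 1558 and 1890 in KITpos against GFRA1neg, and 628 and 1709 in P6gonocyte against GFRA1pos. It gave 1807 and 2072 in KITpos against GFRA1pos, and 955 and 2160 in P6gonocyte against GFRA1neg; this threshold asks for more than 0 change, so fewer genes pass by construction. Limma voom with sample quality weights gave 1802 lower genes in GFRA1pos against GFRA1neg. The 4 libraries highest in spermatid transcripts were GFRA1neg replicate 2 (score 6.39), GFRA1pos replicates 2 (6.31) and 4 (5.67) and KITpos replicate 1 (5.97). Without them 753 genes were higher and 515 lower in GFRA1pos than GFRA1neg, with fewer libraries in the test, above all in GFRA1pos. In P6gonocyte against GFRA1pos 1850 were then higher and 2121 lower. Of the 6060 genes called there with all libraries, 3789 kept their call, and 8 changed sign with 0 called the opposite way. With an estimated correlation 7, 2 and 0 lists were called in the 3 comparisons. With GFRA1neg libraries split 2 and 2, the median overlaps of the adult steps were 173.5, 293, 163 and 63.

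Leaving out each library in turn gave 839 to 1134 higher and 705 to 1039 lower genes in GFRA1pos against GFRA1neg, 3037 to 3343 and 3173 to 3644 in KITpos against GFRA1neg, and 2198 to 2449 and 2833 to 3306 in P6gonocyte against GFRA1pos. Lists called ranged from 9 to 13, 13 to 14 and 11 to 13. With the replicate number as a block, 1292 and 1292, 3351 and 3507, and 2915 and 3494 genes were called. Libraries of GFRA1pos and GFRA1neg with the same number had correlated deviations of 0.44, 0.49, 0.29 and 0.07, and the labels do not say that they are pairs. Over the alternatives fixed before the data were seen, 35 of 348 named results called lost the call other than by the fold threshold or the estimated correlation, and 0 reversed. Of 36 list calls 6 were lost in this way. Among the alternatives chosen later, leaving out genes that track the spermatid score took the lists called in P6gonocyte against GFRA1pos from 11 to 9: the spermatid (0.16) and spermatocyte (0.16) lists, most of whose own genes it removes, were not called.

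Splitting the libraries into other groups of the same sizes tested chance. Libraries were treated as unpaired, and in GFRA1pos against GFRA1neg the highest other split put replicates 1 and 3 of both groups against 2 and 4. On that footing, for genes, the real split called more than any other split run in each comparison. The counts were 2185 in GFRA1pos against GFRA1neg (highest other split 405), 6969 in KITpos against GFRA1neg (5189) and 6060 in P6gonocyte against GFRA1pos (763). They were 7507 in KITpos against GFRA1pos (5690) and 6741 in P6gonocyte against GFRA1neg (0). There were 35 splits per comparison, or a sample of 100 where KITpos was compared. The highest other splits with KITpos kept all libraries of the other group together, so they hold a part of the real difference. Chance is unlikely on this count but not excluded, with 35 splits and a test chosen after the results were seen. For the number of lists called, the splits did not exclude chance in GFRA1pos against GFRA1neg (12, highest other 15). Nor did they in P6gonocyte against GFRA1pos (11, highest other 11). In each, 4 of 35 splits called as many, the real one included. That is no evidence for chance, because a split of 3 libraries and 1 keeps a part of the real difference. Such splits called 7 to 15 and 5 to 11 lists in these comparisons. Splits of 2 and 2 called 1 to 6 and 0 to 6. In KITpos against GFRA1neg 3 of 100 splits called 13 lists or more, the real one included, and 1 other split called 14. The split with 14 put all GFRA1neg libraries with KITpos replicate 3, so it too keeps a part of the real difference. The number of lists called therefore does not decide on chance there either.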

Other observations

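Readings in this part were formed only after the results were seen, and the hypotheses name tests not made here. Early response and feedback genes (Egr2, Dusp6, Dusp4) rose together with Gfra1, Etv5 and Eomes in GFRA1pos, while Neurog3, Rarg and Lin28a fell. The dissociation and heat stress list, which holds early response genes such as Fos, was also called up in GFRA1pos (adjusted p = 0.019, and 0.18 with an estimated correlation), so signalling in the animal and a response to dissociation were not told apart. Measuring these genes after dissociation with transcription blocked would test it. In KITpos, Stra8 and Rhox13 rose beside falls of Zbtb16, Ret and Lin28a.

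Mitosis genes rose in both GFRA1pos and KITpos against GFRA1neg, with the estimated correlation too. DNA replication genes rose in both, but that list had adjusted p = 0.075 in KITpos with an estimated correlation. A candidate explanation is that GFRA1neg cells cycle less than both neighbours, but the 2 comparisons share GFRA1neg, so a level peculiar to those libraries would give the same picture. Across genes the covariance of the steps, 0.187, lay over the 0.087 that sharing alone gave in simulated unchanged groups. Their correlation, 0.216, cannot be set against the simulated 0.517, because the simulated groups hold no real changes. Genes called in both were 388 higher and 565 lower in like direction and 298 and 132 opposed. With GFRA1neg split 2 and 2 these became 173.5, 293, 163 and 63, where independent lists would share means of 110, 106, 121 and 97. A count of cells in S phase in the 3 sorts would test the hypothesis.

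Ribosomal protein and oxidative phosphorylation transcripts rose in KITpos, though the lists had adjusted p = 0.30 and 0.29 with an estimated correlation. The rise stayed without the 2 abundant rows, at medians of 0.948 and 0.922, but a cause that their differing share reflects was not tested. Genes of like length and GC content had medians of 0.26 and 0.32 against 1.00 and 0.98, with upper limits of 0.50 and 0.568. That test was read as undecided, so the share of length in the rise was left open. Protein synthesis measured per cell, or spike-ins of known lengths, would show how large that share is.

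Leydig markers were higher in KITpos, where Insl3 had 14.1 CPM ± 12.1 (SD, n = 5) and Cyp17a1 10.1 ± 5.9, but the list was not called (adjusted p = 0.052, 0.57 with an estimated correlation, and as low as 0.0099 without a count filter). Of its 12 genes none is in another list, and 11 had at least 1 CPM in KITpos and 6 in GFRA1pos. Leydig RNA is a candidate source for these genes. The digestion was meant to remove interstitial cells and the TERT gate should exclude them, but interstitial cells can carry Kit. Sertoli markers also moved in KITpos (7 higher and 2 lower of 16), so a wider share of somatic RNA is possible too. Sorting with a Leydig surface marker would test it.

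Sertoli markers peaked in 1 P6gonocyte library for 16 of 16 genes, and that library also had the lowest Pou5f1, but the other 3 libraries, at scores of 2.30 to 2.43, also lay over every GFRA1pos library (1.05 to 1.15). Sertoli cells passing the sort and expression by the germ cells themselves both remain possible. P6gonocyte replicate 2 also had the highest Leydig (1.58) and myoid (2.13) scores of its group, though neither list was called. A wider share of somatic RNA was not tested. In situ hybridization for Aldh1a1 with OCT4-GFP at postnatal day 6 would show which cells hold it.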
